A study of Rattus norvegicus with 8 samples.

How the data were processed

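DNA methylation was measured by reduced representation bisulfite sequencing in 8 libraries of male Sprague Dawley rats, 4 from hippocampus and 4 from hypothalamus, all from the arm that received the omega-3 diet together with fructose. Per the labels' protocols, genomic DNA was digested with MspI, ligated to barcoded adapters, size-selected and bisulfite-treated before sequencing on an Illumina instrument. Per the submitters' processing notes, the reads were aligned to the rn5 assembly with a pipeline that names Bowtie. The version of Bowtie, the methylation caller, the trimming, the treatment of duplicate reads and any coverage filter are not given in the sources used here. Bisulfite treatment reads 5-methylcytosine and 5-hydroxymethylcytosine alike, so that every level below is the sum of both, and hydroxymethylcytosine is abundant in brain. Cytosines that escape conversion are read as methylated.

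The deposited files give, for each cytosine on either strand, its context (CG, CHG or CHH), the methylation level as a fraction from 0 to 1, and the counts of methylated reads and of all reads. At most 4 lines per file carry none of these contexts. In these deposited counts, every listed cytosine had at least 10 reads in each library and at most 8030, and every level equalled methylated over total reads within rounding. No normalization was applied by the authors to these counts, as far as the values show. The number of listed cytosines therefore depends on depth: the shallowest library, hypothalamus replicate 4, listed 4516666 cytosines and the others 9262735 to 10894215. A site not listed in a library was treated as not measured, never as unmethylated. A minimum of 5 reads per site, planned as an alternative, could not change any value, because no listed site had fewer than 10 reads.

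Levels and counts were taken from the files as follows. The mean CG, CHG and CHH level of a library is the mean over its listed sites of 10 or more reads, each site weighted equally. The few listed mitochondrial sites are included in these means. For tests, the methylated and total reads at both strands of a CpG were summed into 1 position, and positions into non-overlapping windows of 200 bp. A window was tested if it had at least 3 CpG positions seen in any library and at least 10 CpG reads in each of the 8 libraries, which left 95289 windows. A CpG position was tested if it had at least 10 reads in every library, which left 535539 positions. Window levels are methylated over total CpG reads of the window, in percent, and are given as mean ± SD over 4 libraries per tissue. Coordinates are 1-based positions of rn5 as the files give them.

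Windows and positions were tested with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood functions on methylated and unmethylated counts. The model held 1 effect per library for its coverage, the share of methylated reads, and the change of that share between tissues. Calls needed a Benjamini-Hochberg adjusted p under 0.05. Single values per library were compared with two-sided exact permutation tests over the 70 assignments of 8 libraries to 4 and 4, which can give no p below 0.0286. Summaries used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, limma 3.58.1 gave an alternative test, and figures were drawn with matplotlib 3.10.9. The labels do not say that libraries of a tissue came from separate animals, although sites outside CG described below argue against a shared animal within a tissue. The p-values measure the spread between these libraries, which may be partly technical. Reads were counted without molecular identifiers, and PCR copies are not independent molecules.

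The model was tested on simulated data before its use: counts for 20000 windows were drawn around the mean levels and coverage of the real windows with a beta-binomial correlation of 0.0121, estimated from the real replicates. Differences of 10, 20, 30 and 40 points, in 50 windows each with mean levels between 35 and 65%, were called in 0, 2, 58 and 92% of windows in the right direction, with 2 false calls among 19800 unchanged windows, of which 4.54% had an unadjusted p under 0.05. The same simulation for 20000 CpG positions called 0, 8, 54 and 92%, with 4 false calls and 5.53% of unchanged positions at an unadjusted p under 0.05. Libraries were simulated without differences in conversion between them, so that these false calls leave out that source of spread. In this simulation, in which few windows changed, differences of 10 and 20 points were thus mostly missed. The real windows that differed had a median difference of 17.1 points, so that the simulated shares cannot be taken as those of the real test.

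The windows named individually follow a rule fixed before the data were examined: the 10 windows with the largest mean difference in each direction among those with an adjusted p under 0.05 and no overlap between the 4 hippocampus and 4 hypothalamus levels. An annotation of rn5 was not used here, since the gene table at hand describes another rat assembly and coordinates were not converted. Promoters, gene bodies and 19 gene lists that had been fixed for them were therefore not analysed here, and windows are named by coordinates alone.

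Incomplete conversion was read from CHH cytosines on the mitochondrial genome, taken as unmethylated. To remove it, the unconverted share u of a library was taken out of a level m as (m - u)/(1 - u). Methylated counts were treated by the same formula with rounding to whole reads, but were kept from turning negative. The removal from counts was therefore not exact at low levels. Windows with a mean level under 20% had a median level of 1.76% before removal, while u reached 2.73% in hippocampus replicate 3. Alternatives planned beforehand were a minimum of 20 reads, windows of 100 and 1000 bp, no minimum of CpG positions, coverage in 3 of 4 libraries per tissue, removal of sites above the 99.9th percentile of coverage, autosomes alone, a common dispersion, limma on log2 ratios with a pseudocount of 2 reads, Fisher's exact test on pooled counts, the replicate number as a block, and leaving out each library in turn. Chosen after the data were seen were CpG positions listed in all 8 libraries for the windows, removal of the unconverted share, thinning of each window to the reads of its shallowest library, and a class of libraries with over 1% unconverted as a term or as a subset.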

Results

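Reduced representation bisulfite sequencing was carried out on the hippocampus, a forebrain structure needed for forming memories, and on the hypothalamus, the brain centre for appetite, body temperature and hormone release. In this assay genomic DNA is cut with MspI, an enzyme whose recognition sequence contains a CpG, so that the sequenced fragments are enriched for CpG-rich DNA. All 8 libraries came from male Sprague Dawley rats, an outbred laboratory stock, that were 2 months old when they began 6 weeks of an omega-3 fatty acid diet with 15% fructose in the drinking water. There were 4 hippocampus and 4 hypothalamus libraries, and the comparison addressed here was the difference in DNA methylation between these brain regions under that shared diet. Each of the 4 hippocampus libraries held between 496247506 and 543731998 read bases over listed cytosines. The hypothalamus libraries held 243661578, 481891900, 269282620 and 75582845 for replicates 1, 2, 3 and 4, so that the depth was lower and more uneven in hypothalamus. Between 1093223 and 1267770 CpG positions were listed in every library other than hypothalamus replicate 4, which had 550302. The median coverage of a listed CpG ran from 15 reads in hypothalamus replicate 4 to 50 reads in hippocampus replicates 1 and 4, and 535539 CpG positions were listed in all 8 libraries.

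The libraries grouped by brain region. Across 95289 windows of 200 bp, the Pearson correlation of CpG methylation levels was 0.974 to 0.993 for pairs of libraries from the same tissue and 0.963 to 0.983 for pairs from different tissues. The mean correlation within tissues exceeded that between tissues by 0.0119, with a two-sided exact permutation p = 0.0286 over 70 assignments of the libraries, the smallest p that 4 against 4 libraries can give. These correlations are across windows, which are not independent replicates. The first principal component of the window levels, with 46.9% of the variance, separated the 4 hippocampus from the 4 hypothalamus libraries. The second component, with 19.9%, set hypothalamus replicate 4, the shallowest library, apart from the rest. No pair of libraries from the same tissue held identical counts. Their mean chi-square per window was 2.15 to 4.22 over the 63234 to 65430 windows with a pooled level of 5 to 95% in the pair, against 1 for counting noise of independent reads, which PCR copies can raise.

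CpG methylation differed between hippocampus and hypothalamus in 6808 of the 95289 windows (7.14%), and in 6144 of these the level was lower in hippocampus. The windows lower in hippocampus had a median level of 58.4% in hippocampus and 80.2% in hypothalamus. The other 664 windows were higher in hippocampus, with medians of 82.4% and 66.9%. A typical difference was partial: the median over all windows that differed was 17.1 points, 2366 windows differed by 20 points or more, and no window went from under 20% in a tissue to over 80% in the other. Of the 2366, 2275 were lower in hippocampus and 91 were higher. In 6518 windows (95.7%) no hippocampus level fell within the range of the hypothalamus levels or the reverse, a separation found in 13.8% of all tested windows and in 2.86% by chance. The test was edgeR's quasi-likelihood test on methylated and unmethylated read counts with a Benjamini-Hochberg adjusted p under 0.05, and 17426 windows had an unadjusted p under 0.05. A window held a median of 247 CpG reads per library, and 60 in its shallowest library.

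**Figure D1:**
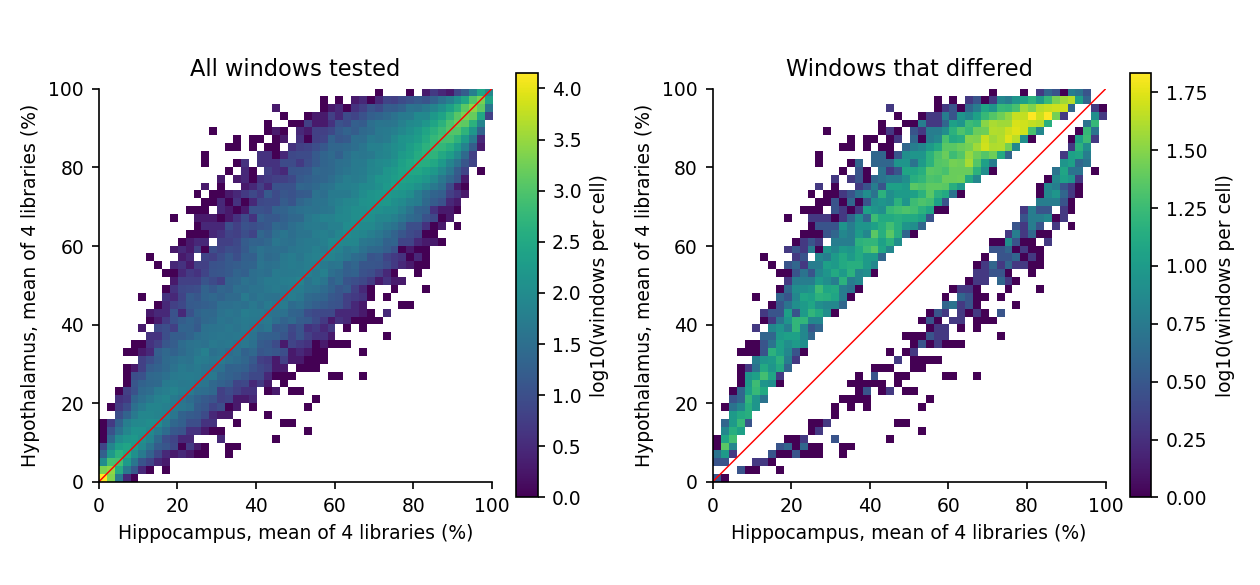
Mean CpG methylation level per 200-bp window in hippocampus (x axis, percent) against hypothalamus (y axis, percent), each the mean of 4 libraries, for all 95289 tested windows on the left and the 6808 windows that differed on the right. Colour gives the log10 of the number of windows per cell of 2 by 2 points and the red line marks equal levels; most windows that differed, 6144 of 6808, lie above the line, where hippocampus was lower.

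The count of windows fell to 4177 without hippocampus replicate 1, to 3751 without hypothalamus replicate 2 and to 3975 without hypothalamus replicate 3, with 91.2 to 93.0% of the windows lower in hippocampus in these 3 tests. The 664 windows higher in hippocampus fell to 339, 380 and 319 without hippocampus replicates 1, 2 and 3 in turn, and to 264 and 350 without hypothalamus replicates 2 and 3. They numbered 223 after thinning and 1098 with the unconverted share removed. The libraries also differed in bisulfite conversion, as read from the unconverted share of CHH cytosines on the mitochondrial genome. Among the 5 libraries with over 1% unconverted, 2 from hippocampus and 3 from hypothalamus, 4283 windows differed, 3202 lower (74.8%) and 1081 higher in hippocampus. Among the 3 libraries with 1% or less, 2 from hippocampus and 1 from hypothalamus, edgeR called 0 windows and 15500 had an unadjusted p under 0.05. This test of 2 against 1 library rests on a single hypothalamus library, so that its count cannot be weighed against the others. The 20 windows named individually differed by at least 25.3 points in these 3 libraries, which were among those used to choose them for large differences. With the class of libraries over 1% unconverted as a term in the model for all 8, 8326 windows differed, 75.3% of them lower in hippocampus.

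The window with the largest difference lay on chromosome 1 (93658801 to 93659000). Its level was 28.0% ± 4.05 (SD, n = 4) in hippocampus and 89.9% ± 4.22 (n = 4) in hypothalamus, a difference of -61.9 points at an adjusted p of 0.000593 in edgeR, read from 32 to 273 CpG reads per library. On chromosome 3 (182769001 to 182769200) the level was 27.9% ± 7.16 in hippocampus and 81.2% ± 7.35 in hypothalamus, with 71 to 516 reads per library. A window on chromosome 10 (24840001 to 24840200) had 35.1% ± 6.71 in hippocampus and 87.7% ± 4.71 in hypothalamus, and a window on chromosome 7 (32071401 to 32071600) with 11 CpG positions had 32.2% ± 7.07 and 84.2% ± 3.12. Levels near full methylation in hypothalamus met levels near 45% in hippocampus on chromosome 4 (195003801 to 195004000), with 94.2% ± 4.10 against 44.6% ± 6.46, and on chromosome 1 (283152801 to 283153000), with 94.5% ± 3.25 against 45.1% ± 6.86. The first of these had as few as 14 reads in a library and the second as few as 33. The lowest hippocampus level among these 10 windows was 18.6% ± 8.03 on chromosome 14 (4824201 to 4824400), where hypothalamus had 66.6% ± 6.92. On chromosome 3 (114129801 to 114130000) hippocampus was lower by 49.1 points. The window on chromosome 19 (36022001 to 36022200) rested on as few as 10 reads in a library and varied widely in hypothalamus, 82.6% ± 18.6 against 27.7% ± 8.61 in hippocampus, and its adjusted p rose from 0.0181 to 0.0787 without hypothalamus replicate 3, while the difference was -54.5 points against -55.0 with it. The window on chromosome 10 (20055001 to 20055200), with 26.4% ± 4.10 in hippocampus and 75.2% ± 11.8 in hypothalamus, had as few as 11 reads in a library, and its adjusted p was 0.0643 after every window was thinned to the reads of its shallowest library, at a difference of -40.9 points against -48.8 before.

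Of the 10 named windows higher in hippocampus, 6 lay at 2 places on chromosome 3, which held 48 of all 664 windows higher in hippocampus. At 176622001 to 176622200 the level was 53.7% ± 4.94 (SD, n = 4) in hippocampus and 13.5% ± 3.23 (n = 4) in hypothalamus, a difference of 40.1 points at an adjusted p of 0.000619 in edgeR. The nearby windows at 176622601 to 176622800 and at 176623801 to 176624000 had 44.5% ± 2.56 and 49.5% ± 10.6 in hippocampus against 10.4% ± 2.19 and 15.1% ± 3.41 in hypothalamus. At 102317401 to 102317600 the level was 66.8% ± 4.13 in hippocampus and 27.4% ± 7.47 in hypothalamus. The windows at 102318201 to 102318400 and at 102318401 to 102318600 had 52.4% ± 2.11 and 54.2% ± 0.379 in hippocampus against 19.2% ± 3.48 and 20.8% ± 3.29 in hypothalamus. Elsewhere, windows on chromosome 15 (42380401 to 42380600), chromosome 16 (58764401 to 58764600), chromosome 5 (133594601 to 133594800) and chromosome 2 (251302201 to 251302400) were higher in hippocampus by 36.6, 34.4, 33.8 and 33.0 points. The adjusted p of the 10 windows ranged from 0.000619 to 0.00551, and between 22 and 1320 reads stood behind each level. No gene is given for any of these windows, because an annotation of the rn5 assembly was not used here.

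**Figure D2:**
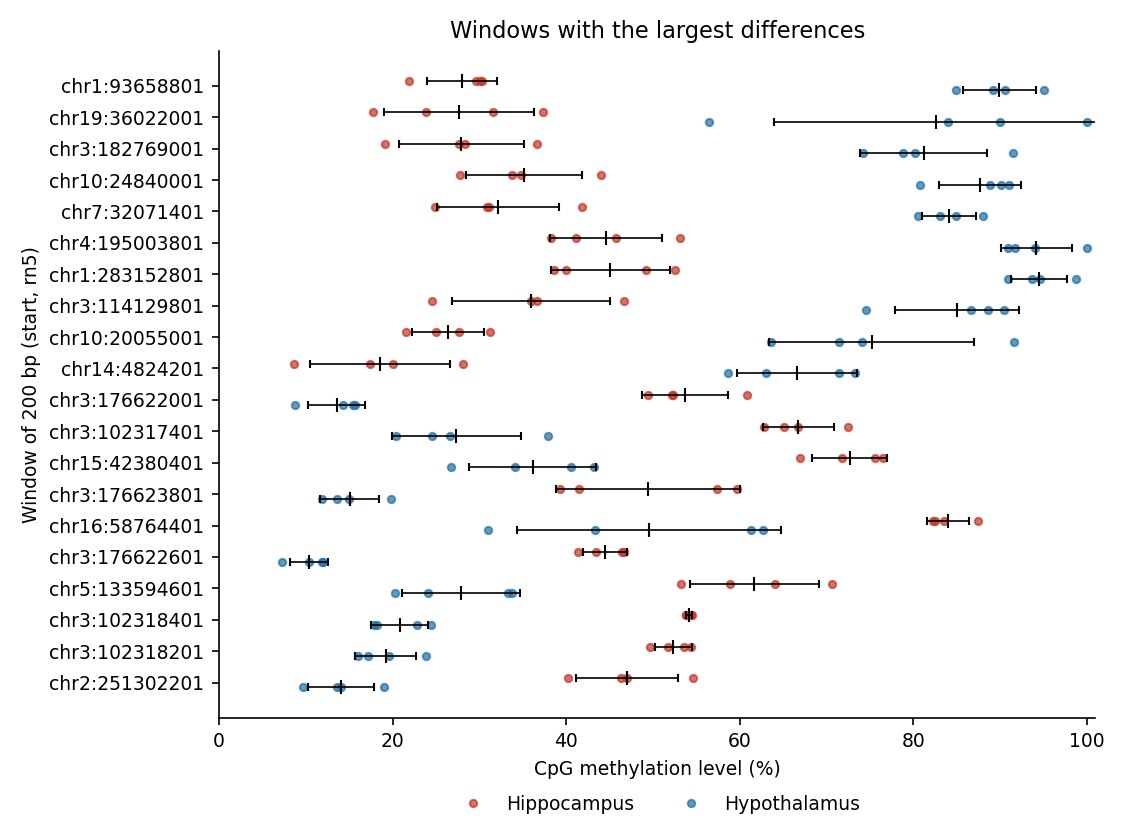
CpG methylation level (x axis, percent) in each of the 4 hippocampus libraries (red) and 4 hypothalamus libraries (blue) for the 10 windows lower in hippocampus (upper rows) and the 10 windows higher in hippocampus (lower rows) with the largest differences; black marks and bars are means ± SD. Windows were chosen for levels that do not overlap between the tissues, and the largest difference is 61.9 points, on chromosome 1.

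The share of windows that differed varied with their methylation level and CpG density. Of 27392 windows with a mean level over both tissues of 20 to 80%, 16.1% differed between hippocampus and hypothalamus, against 5.08% of the 38791 windows above 80% and 1.51% of the 29106 windows under 20%. A difference itself moves this mean toward the middle, and 3091 of the 6144 windows lower in hippocampus (50.3%) were over 80% in hypothalamus. The share under 20% also depended on whether the unconverted share was removed, a step that kept methylated counts from turning negative. Over 30000 randomly chosen windows, 135 of 2108 calls had a mean level under 20%, and 404 of 2944 with the unconverted share removed. CpG-dense windows with 15 or more CpG positions were nearly unmethylated in both tissues, at a mean of 3.69% in hippocampus and 3.67% in hypothalamus, and 13 of 5344 (0.243%) differed. Windows with 3 to 4 CpG positions had means of 67.5% and 69.6%, and 8.64% of them differed. Among windows of 20 to 80% the share was 16.2% with 3 to 9 CpG positions and 10.6% with 10 or more. On the autosomes 6.47% (chromosomes 3 and 10) to 8.62% (chromosome 19) of windows differed, and on every chromosome at least 84.7% of those were lower in hippocampus. On the X chromosome 36 of 1047 windows (3.44%) differed, 34 of them lower in hippocampus. Differences between chromosomes or between classes of windows were not tested.

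**Figure D3:**
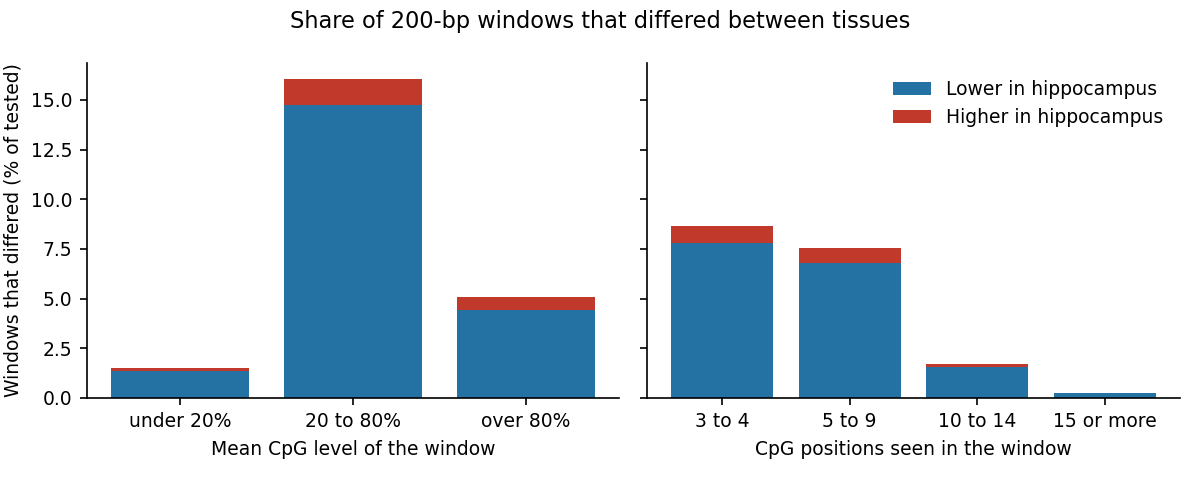
Share of tested 200-bp windows that differed between the tissues (y axis, percent) by the mean CpG level of the window (left) and by the number of CpG positions seen in it (right), split into windows lower (blue) and higher (red) in hippocampus. The share peaks at 16.1% for windows of 20 to 80% and falls to 0.243% for windows with 15 or more CpG positions. The unconverted share was not removed here.

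At single CpG positions the same direction prevailed. Of the 535539 CpG positions with at least 10 reads in all 8 libraries, 18460 (3.45%) differed in edgeR's test, 17131 lower and 1329 higher in hippocampus, with a median difference of 23.1 points. Of these positions, 11343 (61.4%) lay in a window that differed. The count was 12200, 8338 and 10629 without hypothalamus replicates 1, 2 and 3 in turn, and it was 5723 of 150535 positions when at least 20 reads were required in every library.

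Over all listed CpG sites, the mean methylation level of hippocampus and hypothalamus was not distinguishable. It was 49.0% ± 1.54 (SD, n = 4) in hippocampus and 49.9% ± 1.43 (n = 4) in hypothalamus, a difference of -0.902 points with an exact permutation p = 0.429. The difference was -0.299 points without hippocampus replicate 1, -1.38 without hippocampus replicate 4, -0.415 without hypothalamus replicate 1 and -1.56 without hypothalamus replicate 4. At the CpG positions listed in all 8 libraries the mean level was 47.6% ± 1.04 against 49.1% ± 0.433, a difference of -1.46 points with an exact permutation p = 0.0571. With the unconverted share of each library removed as well, a step chosen after the data were seen, the levels were 46.8% ± 0.435 and 48.3% ± 0.234 and the difference of -1.50 points had the smallest possible exact permutation p, 0.0286. The mean level was thus lower in hippocampus by under 2 points on each of these scales, and the exact test passed its threshold on the last of them.

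Outside CpG, the mean methylation levels of whole libraries were low in both tissues, and no difference between hippocampus and hypothalamus was detectable in these means. CHG cytosines, where H is any base but G, had a mean level over sites of 1.96% ± 1.24 (SD, n = 4) in hippocampus and 1.72% ± 0.399 (n = 4) in hypothalamus, with an exact permutation p = 0.714. CHH cytosines had a mean level over sites of 2.02% ± 1.13 in hippocampus and 1.98% ± 0.441 in hypothalamus, with an exact permutation p = 1. Mitochondrial CHH cytosines, read here as a measure of incomplete conversion from 67 to 80 positions per library, were unconverted in 1.52% ± 1.32 of reads in hippocampus and 1.49% ± 0.587 in hypothalamus. Among the libraries this share ran from 0.339% (95% Wilson interval 0.320 to 0.360, which covers counting error only) to 2.73% (2.68 to 2.79). CHH cytosines followed by A are the CA context in which brain non-CG methylation is mostly found. Their mean level over sites stood above the share of methylated reads at mitochondrial CA by 1.66 points ± 0.131 in hippocampus and 1.49 points ± 0.244 in hypothalamus. The difference between tissues was 0.167 points with an exact permutation p = 0.286. With both levels weighted by reads it was 0.157 points, with an exact permutation p = 0.286. The CA level was above the mitochondrial level in 8 of 8 libraries, by 1.20 to 1.81 points. CHH cytosines followed by C differed from their mitochondrial level by 0.0395 points ± 0.0538 in hippocampus and -0.229 points ± 0.299 in hypothalamus, and those followed by T by 0.613 points ± 0.0564 and 0.619 points ± 0.0700. At C the difference was -0.565 points in hypothalamus replicate 1, -0.394 in hypothalamus replicate 3 and -0.0349 to 0.0917 in the others. The mitochondrial share may therefore overstate the unconverted share of hypothalamus replicates 1 and 3. These libraries also had the smallest CA values above the mitochondrial level, 1.20 and 1.37 points.

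**Figure D4:**
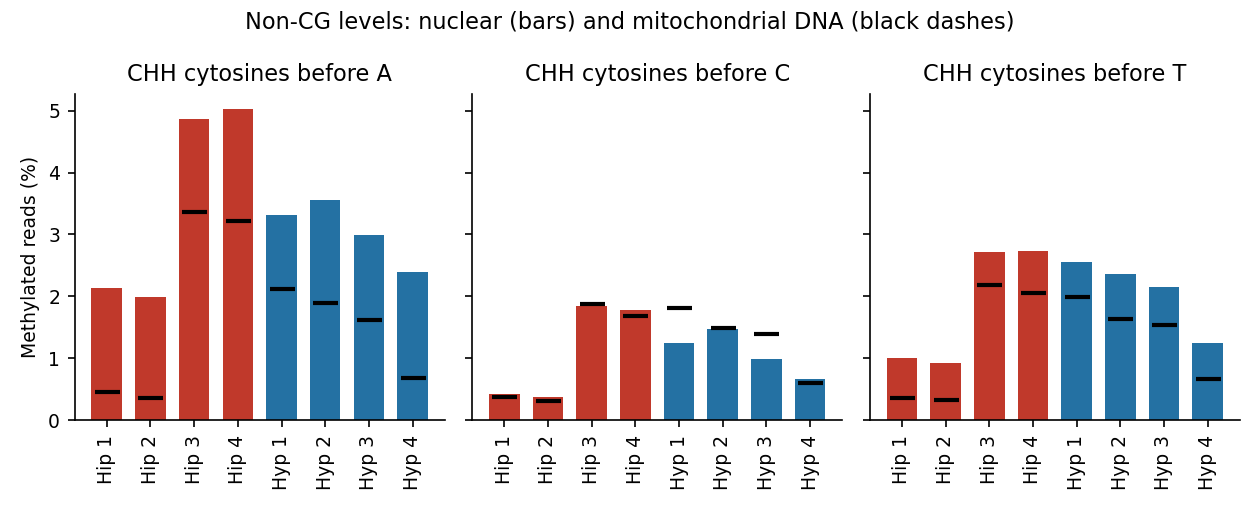
Mean level (bars, y axis, percent) over listed CHH cytosines followed by A, C or T in each of the 4 hippocampus (Hip, red) and 4 hypothalamus (Hyp, blue) libraries. In the bars each site has equal weight, and the few mitochondrial sites are included, although the labels read methylated reads and nuclear. Black dashes are the share of methylated reads for the same context on the mitochondrial genome. The CA bars of the libraries range from 2.00 to 5.02% and stand 1.20 to 1.81 points above the dashes in all 8 libraries.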

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

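The tests reported here of the libraries' non-CG levels against tissue and conversion were chosen after those levels had been seen, and so were the removal of the unconverted share, the thinning and the restriction to shared CpG positions. The test on the X chromosome was written down before its values were seen.

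In the window on chromosome 1 from 93658801 to 93659000, hippocampus replicate 1 stood far from the other hippocampus libraries. Its CpG level was 21.951% (95% Wilson interval 17.2 to 27.5, 246 reads), while the others lay at 29.7 to 30.3%. All 4 hippocampus levels were far below the hypothalamus levels in this window. With 50 groups of 4 libraries examined, 2.5 such cases arise by chance and 1 was found. Hippocampus replicate 1 was also the lowest hippocampus library in each named window lower in hippocampus other than that on chromosome 3 from 114129801. On chromosome 14 from 4824201, for example, it was at 8.66% and the others at 17.4 to 28.1%. On the first principal component the hippocampus libraries lay at 4.52, 3.57, 3.23 and 2.18 for replicates 1 to 4. The cause of this order was not tested.

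Far more windows were lower (6144) than higher (664) in hippocampus, and 3 technical explanations were tested. Thinning every window to the reads of its shallowest library left 92.97% of 3173 windows lower in hippocampus, removing the unconverted share left 88.52% of 9566, and using only CpG positions listed in all 8 libraries left 89.56% of 5249. Each of these argues against depth, incomplete conversion or unequal site lists as the whole cause of the skew. With the conversion class as a term the share was 75.3%, because windows called higher in hippocampus rose to 2054 while those called lower numbered 6272, against 6144 without the term. A difference in cell composition or in methylation between hippocampus and hypothalamus stays open and was not tested.

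Non-CG levels differed between libraries of the same tissue, with mean CHH levels of 1.01 to 3.01% in hippocampus and 1.37 to 2.35% in hypothalamus. The SD over 8 libraries of the CA level was 1.16 points, and 0.202 points after the mitochondrial CA level of the same library was subtracted, a ratio of 0.174. The tissue gave no such separation, with an exact permutation p of 1 for the CHH level. Incomplete bisulfite conversion is therefore a candidate explanation for most of the spread between libraries, and which step of library making it came from was not tested.

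Among cytosines outside CG, which the tissue comparison used only as means over many sites, 464 autosomal ones were at 70% or more in some library and at 20% or less in another, as sites of a sequence variant between animals would be. Over these sites hippocampus replicate 3 correlated with hypothalamus replicate 2 (r = 0.956) and hippocampus replicate 4 with hypothalamus replicate 3 (r = 0.949), while the highest of the other 14 pairs across tissues was 0.188. Pairs of libraries from the same tissue correlated at -0.105 to 0.141, which argues against any 2 libraries of a tissue from the same animal. On the X chromosome, which took no part in finding the 2 pairs across tissues, both of these reached at least 0.970 and the highest other pair across tissues 0.7563, although over only 5 sites. The libraries of these 2 pairs may therefore come from the same animals, which would make 6 animals rather than 8. The correlations are across sites, which are not independent, and the same DNA in both libraries of a pair is argued against by their CpG levels, which lay apart on the first principal component at 3.23 against -2.71 and 2.18 against -3.17.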

How the results depend on the processing

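Removal of the unconverted share, shared CpG positions for windows, thinning and the conversion classes were chosen after the data were seen. The excess of windows lower in hippocampus held in each setting that called any window, at 72.8 to 94.8% of calls. From 6808 of 95289 (7.14%), the count of windows fell to 3750 of 83705 (4.48%) at 100 bp and to 3173 after thinning. With no minimum of CpG positions it rose to 11807, but 170920 windows were tested and the share called was 6.91%. The count rose to 27455 with Fisher's exact test, which ignores the spread between replicates. It was 4283 among the 5 libraries over 1% unconverted and 0 among the other 3, a test of 2 against 1 library in which edgeR had 15500 at an unadjusted p under 0.05. Leaving out a library in turn gave 3751 to 6448 windows. The remaining 10 settings stayed within 1.5 times 6808 in count. Among them, coverage in 3 of 4 libraries per tissue called 7574 of 148844 tested windows (5.09%). Sites numbered 5723 at 20 reads, with fewer sites tested, 52835 with Fisher's exact test, and 8338 to 22363 without a library. The replicate numbers did not pair the libraries: same-number deviations correlated at 0.0554, -0.0958, -0.0963 and 0.00119. The highest of the 16 correlations across tissues were 0.178 for hippocampus replicate 3 with hypothalamus replicate 2 and 0.165 for hippocampus replicate 4 with hypothalamus replicate 3. With the number as a block 3567 windows, 187 of them higher in hippocampus and 3468 among the 6808, and 14466 sites were called.

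The CG difference was -0.198 to -1.56 points in 16 settings, and its exact test passed only at shared sites with the unconverted share removed (-1.50). CHG and CHH passed no exact test. Their largest differences, 1.14 and 0.820 points, came in the 5 libraries over 1% unconverted, each at the smallest exact p of 2 against 3 libraries, 0.100. Their sign turned among the 3 libraries of 1% or less unconverted, to -0.317 and -0.324, where the smallest exact p is 0.333, and without single libraries, which gave -0.125 to 0.610 for CHG and -0.282 to 0.385 for CHH. CHG turned without hippocampus replicate 3 (-0.125) or 4 (-0.119), and CHH without these (-0.273 and -0.282) or hypothalamus replicate 4 (-0.154). The causes were not tested. The grouping of libraries by tissue held in all 9 alternatives.

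The 20 named windows were chosen for levels that do not overlap between the tissues, so that leaving out libraries cannot turn their direction. Their adjusted p was 0.05 or more in 24 of 451 values, 20 of them in the 3 libraries of 1% or less, where they differed by at least 25.3 points, and 3 for the window on chromosome 19 from 36022001 (-55.0 points with the block, -49.5 in the 5 libraries over 1%, -54.5 without hypothalamus replicate 3) and 1 after thinning for the window on chromosome 10 from 20055001. Windows of 100 and 1000 bp give no value for a 200-bp window, a minimum of 5 reads removes nothing, and promoters, gene bodies and gene lists with their alternatives were not run. The shallowest library, hypothalamus replicate 4, had a median of 15 reads per CpG, and 5594 windows were called without it.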

Other observations

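The test of the split by conversion and the comparison of splits over windows were chosen after results had been seen, as were the joining of windows into regions and the count per megabase. The tests on splits over CpG positions and on CA in the windows that differed were written down before their values were seen.

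Windows that differed lay side by side in places. With windows of the same direction joined when their starts were at most 1000 bp apart, 632 regions of 2 or more windows were lower and 46 were higher in hippocampus. The region on chromosome 3 from 176622001 to 176624000 held the most windows, 5 of 5 tested, with 36 CpG positions at 37.2% ± 2.99 (SD, n = 4) in hippocampus and 9.85% ± 2.18 (n = 4) in hypothalamus. A further region on chromosome 3, from 102317401 to 102318600, was at 55.2% ± 1.94 in hippocampus and 21.1% ± 2.24 in hypothalamus. On chromosome 5 a region higher in hippocampus, from 133592601 to 133593200, was at 27.2% ± 3.87 and 8.56% ± 2.17. Among regions lower in hippocampus, 4 adjacent windows on chromosome 10 from 102440401 to 102441200 were at 51.0% ± 4.42 in hippocampus and 80.2% ± 3.55 in hypothalamus. On chromosome 6, from 139010801 to 139011400, hippocampus was at 49.6% ± 5.95 and hypothalamus at 90.4% ± 2.73, and on chromosome 4, from 243313601 to 243314200, at 26.5% ± 3.39 and 63.3% ± 7.23. On chromosome 10, from 106420401 to 106421800, both tissues were low, at 7.86% ± 0.684 and 17.1% ± 1.95.

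Windows that differed were also dense in single megabases. On chromosome 18, from 64000001 to 65000000, 18 of 38 tested windows differed (47.4%), and all 18 were lower in hippocampus. On chromosome 10, from 20000001 to 21000000, 19 of 79 differed, all lower in hippocampus, and on chromosome 5, from 173000001 to 174000000, 32 of 185 differed, 30 of them lower. These 3 of 1499 megabases passed a binomial test against the share over all windows, with adjusted p of 2.92e-08, 0.00151 and 0.00151. Neighbouring windows are not independent, so that these p-values are too small.

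Methylation at CA was compared in the same windows, with the CA level of windows that did not differ subtracted in each library. Here CA covered both CHG and CHH cytosines followed by A, unlike the CHH sites of the mean CA level above. Only sites listed in all 8 libraries and under 50% in every library were kept, so that the most methylated CA sites were left out. In windows lower in hippocampus at CpG, CA stood 0.0212 points ± 0.0406 (SD, n = 4) above that level in hippocampus and 0.609 points ± 0.0262 (n = 4) in hypothalamus, a difference of -0.5873 points with the smallest possible exact permutation p, 0.0286. In windows higher in hippocampus at CpG, CA stood 0.738 points ± 0.0603 above it in hippocampus and 0.365 points ± 0.0279 in hypothalamus, a difference of 0.3734 points with an exact permutation p of 0.0286. CA and CpG methylation thus may move together in the windows where the tissues differ, a hypothesis that rests on 57517 and 6101 CA sites. An unconverted share that is equal over a whole library would be largely removed by the subtraction. Whether it was equal, or conversion differed between windows, was not tested.

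Splits of the 8 libraries other than by tissue were compared over 30000 randomly chosen windows and as many CpG positions. For windows the split by tissue called 2108 and the highest of the other 34 called 999, so that 1 of 35 splits reached the value of the tissues, the fewest possible. If all 8 libraries were exchangeable, 1 of 35 splits would lie under the 0.05 threshold. The comparison for windows was, however, chosen after results had been seen. If 2 pairs of them share an animal, as the non-CG sites would allow, the splits are not fully exchangeable, and no test here took such pairs into account. That other split put hippocampus replicates 1 and 2 with hypothalamus replicates 3 and 4, the 4 libraries of lowest unconverted share, so that it follows a technical structure. Of its 999 windows, 99.8% had a mean level under 20%, against 6.40% of the 2108. With the unconverted share removed it called 0 windows while the tissues called 2944, of which 13.7% had a mean level under 20%. The split follows the share that was removed, and counts were kept from falling under 0. This loss of calls was thus largely fixed in advance. Incomplete bisulfite conversion may set apart the low-methylated windows of these libraries, which this removal cannot decide. For CpG positions the tissues called 1017 and the highest other split 27, again 1 of 35 splits reaching the value of the tissues.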
